A study of Mus musculus with 39 samples.

How the data were processed

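RNA from the interscapular brown fat of male mice was sequenced as 16 libraries, 4 for each combination of Cre label and housing temperature (22 or 30 °C). Per the labels' protocols these were stranded polyA libraries read as single reads of 75 cycles. The deposited table gives 1 signal value per gene and library: per the submitters' processing notes, the authors counted reads with kallisto against mm10 and normalised between libraries with DESeq2. The annotation version, filters and tool versions are not given in the sources used here. The values are neither whole numbers nor multiples of a step per library, so reads could not be recovered and raw depth is unknown. Dividing out library size also means that a change in total RNA between groups would not be seen. The 16 sample columns were matched to samples by name and 0 were left unused. Of 24116 gene entries, 26 had symbols turned into dates, which were restored, and 14 had no symbol.

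The authors' peak list covers BCL6 binding in Cre-negative brown fat. Per the file headers it was annotated with HOMER on mm10, and per the submitters' processing notes reads were aligned with Bowtie2. The deposited score of each peak is the value HOMER printed, its scale and the calling threshold and control library are not given in the sources used here, and it was used only to rank peaks. The ChIP samples for H3K27ac, ERRa, BCL6 in Cre-labelled fat and input were not analysed here.

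Since the deposited values are normalised, tests ran on log2(value + 1), and all fold changes are on that scale, which understates the change of low genes. Genes with a mean of at least 10 over the 16 libraries were kept, 13176 in all. A linear model with 1 mean per group was fitted to all 16 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend with the mean (prior degrees of freedom 4.83, residual 12). Libraries labelled Cre-positive are called Cre-labelled. The comparisons were Cre-labelled minus control at each temperature, 30 °C minus 22 °C within each label, and the interaction. P-values were adjusted by Benjamini-Hochberg over all genes kept, with a threshold of 0.05. Bcl6 also had a two-sided exact permutation test. Gene lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. No list passed with the estimate. Member counts are also given adjusted over the list alone.

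The comparisons, tests, alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. The lists cover brown fat identity, fatty acid oxidation, respiratory chain subunits, citric acid cycle, white fat enriched, skeletal muscle, lipogenesis, lipolysis lipid droplet, cholesterol synthesis, extracellular matrix, macrophage markers, lymphocyte markers, endothelial markers, mural smooth muscle markers, adipocyte progenitor markers, schwann neural markers, erythrocyte markers, apoptosis regulators, genes known to be repressed by BCL6, circadian clock, interferon response, unfolded protein stress, immediate early, cell cycle, glycolysis, branched-chain amino acid breakdown, creatine calcium cycling, nuclear receptors and insulin igf signaling. For each comparison the rule takes Bcl6 and the 6 genes with the largest and the 6 with the smallest log2 difference among those past the threshold. Such genes need a mean of at least 100 in the higher group and, except for the interaction, no overlap between the groups, and predicted or clone names are left out. For lists it takes up to 4 members with the smallest adjusted p. A gene that the rule takes for the interaction and 2 of the 5 highest peaks are not reported here. Which lists have members named in the text, and how many, was decided after the list results were seen, always in order of adjusted p. Ucp1 in the comparison of temperatures in controls, Acot2 and the genes of the last observations were chosen after their values were seen.

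Peaks were assigned to the gene with the nearest transcription start in the authors' annotation, and genes with a peak within 10 kb were counted among genes higher, lower and not past the threshold, with two-sided Fisher's exact tests adjusted over 6 tests. The direct test of higher against lower genes was added after the data were seen. Gene coordinates come from a RefSeq table of assembly GRCm38.p6, the build named mm10, and peak coordinates are as deposited. No genome sequence was used.

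The limma and camera steps and the peak counts were tested on simulated data with known answers, the peak step after its first use on the real data. With 200 of 13176 genes changed, the test recovered 58.2 (interaction) to 85.1% (temperature in Cre-labelled libraries) of those changed by a log2 size of 1, 92.5 to 97.01% at 2 and 98.5 to 100% at 4 over the 5 comparisons. Unchanged genes made up 2.87% (interaction) to 6.73% (genotype at 30 °C) of the genes called.

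Alternatives were a pseudocount of 8, no filter, a mean of at least 50, quantile normalization, only the groups compared, the replicate number as a block, no trend, robust estimation and each library left out. For lists the estimated correlation was tried, for the overlap and the peaks a threshold of 0.01, and for the peaks windows of 1 and 50 kb and the higher-scoring part of the list. After seeing the data, the 2 libraries at 22 °C with fewest genes above 0 were left out together, the skeletal muscle score was added as a covariate, the list tests were repeated with each library left out, and the overlap of the genotype differences was counted from separate fits for each temperature.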

Results

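RNA was measured in interscapular brown fat, the heat-producing fat depot between the shoulder blades, of male C57BL/6J mice whose Bcl6 gene is flanked by recombination sites for Cre. Bcl6 encodes a transcriptional repressor. Mice without Cre served as controls, and the other mice carried Cre under the promoter of Ucp1, the uncoupling protein that defines brown adipocytes. Both genotypes were housed at 22 °C or at 30 °C, a temperature at which mice need little extra heat, which gave 4 groups of 4 libraries, 16 in all. The labels do not say that the 4 libraries of a group came from separate animals, so the p-values given here measure the spread between these samples. Totals of normalised counts ran from 12064137 to 13516936 in the control libraries and from 10122739 to 12867466 in the Cre-labelled libraries at 22 °C. At 30 °C they ran from 9387313 to 9975035 and from 8867615 to 9479495. The number of genes with a value above 0 ran from 14311 to 16849, lowest in control 22 °C library 1 (14311) and Cre-labelled 22 °C library 2 (15226), the 2 sparsest, and no 2 libraries held identical values. Depth in reads is unknown, so no counting interval is given. A list of 3022 BCL6 binding sites in Cre-negative brown fat was used beside the RNA.

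Bcl6 itself (Entrez 12053, chr16 23965050-23988866, mm10) was higher, not lower, in the libraries labelled Cre-positive. At 30 °C they held 4466 ± 853 normalised counts against 1847 ± 608 in the controls (SD, n = 4 each, 2.50-fold, log2 difference 1.32, SE 0.27, limma adjusted p = 0.00438). The 4 Cre-labelled values were 3269, 4451, 5159 and 4985, and the 4 control values 2340.4, 2266, 1763 and 1020.1. At 22 °C the means were 3305 ± 514 and 1079 ± 509.9 (3.25-fold, log2 difference 1.70, SE 0.27, limma adjusted p = 8.25e-04), with 3263, 2671, 3362 and 3927 in the Cre-labelled libraries and 916, 799, 764 and 1838 in the controls. The groups did not overlap at either temperature, which gave a two-sided exact permutation p of 0.0286 each time, the smallest that 4 against 4 allow. This direction is not what a loss of RNA from the whole Bcl6 gene would give. The deleted part of the gene is not given in the sources used here and the values are sums over the whole gene, so they do not check whether that part was lost, and whole tissue also holds cells without Cre. Directions by genotype are therefore given throughout for the libraries labelled Cre-positive. Between temperatures Bcl6 was 1.74-fold higher at 30 °C than at 22 °C in controls (log2 difference 0.80, SE 0.27, limma adjusted p = 0.0253), but the groups overlapped (exact permutation p = 0.0857) and the call was lost without libraries 1, 2 or 3 (control 22 °C), 1 or 2 (control 30 °C), in the groups compared alone, without the 2 sparsest libraries or with the muscle covariate (adjusted p = 0.0539 to 0.165). In Cre-labelled libraries the same difference was 0.43 (limma adjusted p = 0.252), and the genotype difference did not pass as different between temperatures (interaction -0.38, adjusted p = 0.792).

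The first question is which genes differ by Cre label in warm-housed mice. At 30 °C the Cre-labelled libraries were highest over controls in Acot1, a cytosolic acyl-CoA thioesterase, with 150.4 ± 68.4 against 9.06 ± 11.05 normalised counts (SD, n = 4 each), a log2 difference of 4.47 (SE 0.59, limma adjusted p = 1.03e-04). Nr4a3, Egr3, Atf3 and Fosb, transcription factors that respond rapidly to stimulation, rose too. Their log2 differences were 3.77, 3.53, 3.53 and 3.51 (limma adjusted p = 0.0164, 0.00359, 5.11e-04 and 0.0132). Egr3 went from 40.1 ± 15.1 to 596 ± 531 and Fosb from 12.1 ± 10.5 to 157 ± 138. Sncg, which encodes gamma-synuclein, rose from 179 ± 20.2 to 1831 ± 441 (log2 difference 3.32, SE 0.17, limma adjusted p = 4.51e-09). In the other direction, Gys2, the liver-type glycogen synthase, fell from 447 ± 41.03 to 25.3 ± 1.89, a log2 difference of -4.09 (SE 0.21, limma adjusted p = 4.51e-09). Kng2, a kininogen, fell from 2496 ± 84.98 to 185 ± 76.7 (14.4-fold lower, limma adjusted p = 1.04e-07). Arhgdig, Fras1, an extracellular matrix protein of basement membranes, Tusc3, a subunit of oligosaccharyltransferase, and Rgs11, a regulator of G-protein signalling, fell as well. Their log2 differences were -4.70, -4.59, -3.86 and -3.79 (limma adjusted p = 4.27e-06, 9.60e-06, 4.70e-09 and 2.60e-07). Acot1, Acot3 and Kng2 have close paralogs whose reads the authors' counting could divide, so their values are uncertain.

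By limma, 745 of 13176 genes were higher and 902 lower in the Cre-labelled libraries at 30 °C, 271 and 206 of them by at least 2-fold, and the groups did not overlap for 22.9% of genes where chance gives 2.86%. Without control 30 °C library 4 the counts were 452 and 559. Without Cre-labelled 30 °C library 1 they were 484 and 598, and without Cre-labelled 30 °C library 4 the higher genes numbered 488. Fitted on the groups compared alone, 1123 were higher. The call for Nr4a3 was lost without control 30 °C libraries 3 or 4 or Cre-labelled 30 °C library 3 (limma adjusted p = 0.0517 to 0.0628).

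**Figure D1:**
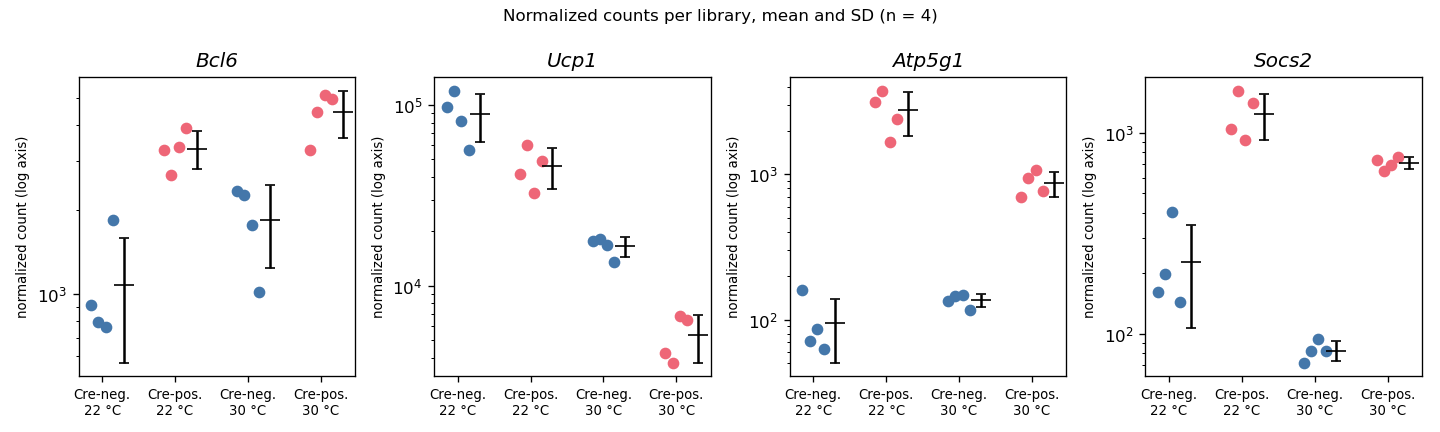
Normalised counts on log axes for Bcl6, Ucp1, Atp5g1 and Socs2 in each of the 16 libraries, in 4 groups by housing temperature and Cre label (points, libraries, and black marks, mean and SD, n = 4). For Bcl6 the 4 libraries labelled Cre-positive lie above the 4 controls at each temperature, at 4466 ± 853 against 1847 ± 608 at 30 °C.

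Genes of mitochondrial fuel use fell together in the Cre-labelled libraries at 30 °C. Of 27 fatty acid oxidation genes measured, 18 were lower and 1 higher (2 higher and 20 lower adjusted over the list alone), with a median log2 difference of -0.58. The list was lower by camera adjusted p = 4.87e-10, and adjusted p = 0.243 with estimated correlation. Among them were Slc25a20, the mitochondrial carnitine carrier (-0.99, limma adjusted p = 4.58e-05), Acaa1b, a peroxisomal thiolase (51.2 ± 16.7 against 163 ± 16.6, adjusted p = 6.87e-04), and the acyl-CoA dehydrogenases Acadl (-0.82) and Acadm (-0.91). The 1 higher member was Acot2, a mitochondrial acyl-CoA thioesterase (0.86, limma adjusted p = 0.00428). Enzymes that break down branched-chain amino acids fell in 15 of 23 and citric acid cycle genes in 13 of 24, 20 and 19 adjusted over the list alone (camera adjusted p = 8.17e-11 and 1.81e-10, adjusted p = 0.137 and 0.243 with estimated correlation). Ppm1k, the phosphatase that activates the branched-chain ketoacid dehydrogenase, stood at -0.88 (limma adjusted p = 1.55e-04), Pccb at -0.67, Ogdh at -0.87, Suclg1 at -0.74 and citrate synthase Cs at -0.69. Subunits of the respiratory chain and ATP synthase moved less, with 6 of 78 lower, 1 higher and a median of -0.19 (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 9.98e-05, adjusted p = 0.604 with estimated correlation). Ndufv1 was among those lower (-0.61, and -0.40 under quantile normalization, as Cs was -0.42 and the median -0.10), and the 1 higher was Atp5g1, a c subunit of ATP synthase, at 869 ± 171 against 136 ± 14.1 (log2 difference 2.65, SE 0.26, limma adjusted p = 6.16e-06).

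Brown fat identity genes were lower in 11 of 29 and higher in 1 (4 higher and 18 lower adjusted over the list alone, camera adjusted p = 7.67e-06, adjusted p = 0.126 with estimated correlation). Ucp1 (chr8 83290348-83298456) fell from 16596 ± 2078 to 5329 ± 1554, 3.20-fold (limma adjusted p = 2.80e-04). The mitochondrial protein Letmd1 stood at -0.87 (limma adjusted p = 7.72e-05) and the fatty acid transporter Slc27a2 at -1.41 (adjusted p = 2.11e-04). Glycolysis genes fell in 9 of 23, 9 adjusted over the list alone (camera adjusted p = 1.01e-04, adjusted p = 0.243 with estimated correlation). Aldoc stood at -3.41, Ldhb at -0.90 and Pfkl at -1.47. Of 18 listed white fat genes, 2 were higher and 2 lower (4 higher and 4 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.363). The higher ones were the imprinted Nnat at 13655 ± 2617 against 1813 ± 593 (limma adjusted p = 6.16e-06), and Mest at 1074 ± 506 against 138 ± 37.8 (adjusted p = 1.72e-04). Slc36a2, an amino acid transporter, was among the lower (-0.67). The listing was not tested. Lipogenesis had 2 of 23 genes higher and 3 lower (2 higher and 6 lower adjusted over the list alone), lipolysis and lipid droplets 3 of 20 lower, and creatine and calcium cycling 2 of 12 lower, 3 of the 12 also on the muscle list (8 and 2 adjusted over the list alone). These lists passed as lower (camera adjusted p = 0.0346, 0.0346 and 0.0344, adjusted p = 0.595, 0.378 and 0.243 with estimated correlation). Lipogenesis no longer passed without libraries 2 (control), 1 or 4 (Cre-labelled), with a mean of at least 50, under quantile normalization or with the muscle covariate (camera adjusted p = 0.0596 to 0.182). Lipolysis did not pass without libraries 2 (control), 1 (Cre-labelled), with a mean of at least 50, under quantile normalization or with the muscle covariate (camera adjusted p = 0.0556 to 0.594), nor creatine and calcium cycling without Cre-labelled library 1 or without the 2 sparsest libraries (adjusted p = 0.0585 to 0.135). The last had a median of -0.43, and 0.03 without that library. Its score was lowest in Cre-labelled 30 °C library 1 (-1.27), where skeletal muscle scored -3.68.

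Macrophage markers rose at 30 °C in the Cre-labelled libraries, 17 of 22 past the threshold and none lower (17 higher and 0 lower adjusted over the list alone), with a median log2 difference of 1.12 (camera adjusted p = 3.06e-11, adjusted p = 0.138 with estimated correlation). Cd68, a lysosomal glycoprotein of macrophages, went from 141 ± 17.4 to 515 ± 264 (limma adjusted p = 0.00122). Lysozyme Lyz2 went from 1241 ± 217 to 4487 ± 2293 (limma adjusted p = 0.00273). Mpeg1 rose by 1.73 and complement C1qb by 1.18. Endothelial markers, lymphocyte markers and interferon response genes rose in 4 of 16, 2 of 13 and 3 of 24 cases, the same counts adjusted over the list alone (camera adjusted p = 9.82e-05, 0.00415 and 2.72e-04, adjusted p = 0.278, 0.243 and 0.378 with estimated correlation). The immediate early list, transcription factors that respond within minutes to stimulation, had 7 of 19 genes higher, 10 adjusted over the list alone (camera adjusted p = 3.72e-05, adjusted p = 0.243 with estimated correlation). Among them were Fosl2 (1.75, limma adjusted p = 4.00e-04) and Egr2 (2.39, adjusted p = 0.00335) besides Atf3 and Egr3. The list scored 2.44 in Cre-labelled 30 °C library 3 and 0.561 to 0.888 in the other 3. Skeletal muscle genes, a mark of neighbouring muscle in a dissected depot, varied widely between libraries. Their score, the mean log2 deviation from each gene's mean, spanned 1.25 to 2.05 in the controls and -3.68 to 2.48 in the Cre-labelled libraries at 30 °C. The list had a median of -1.36 with 1 of 42 members past the threshold, none adjusted over the list alone (camera adjusted p = 0.0248, adjusted p = 0.704 with estimated correlation). That member was Actn2, an actin crosslinker of muscle (-2.86, limma adjusted p = 0.0452), whose call was lost without libraries 2, 3 or 4 (control 22 °C), 1, 2, 3 or 4 (control 30 °C), 1 or 4 (Cre-labelled 30 °C), without the filter, without the trend or with robust estimation (adjusted p = 0.0532 to 0.158). The list did not pass without libraries 1 (control), 1 or 4 (Cre-labelled) or with a mean of at least 50 (camera adjusted p = 0.0627 to 0.896), and its median was 0.25, -2.26 and -2.18 without Cre-labelled libraries 1, 2 and 3.

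Among genes known from other cells to be repressed by BCL6, 4 of 23 were higher and 1 lower (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0346, adjusted p = 0.240 with estimated correlation). Socs2, a suppressor of cytokine signalling, rose from 82.2 ± 9.26 to 708 ± 50.04 (8.55-fold, SE 0.25 on the log2 scale, limma adjusted p = 6.67e-07). Myd88 rose by 0.62 (limma adjusted p = 0.00110) and Id2 fell by 0.89 (adjusted p = 5.34e-04). Insulin and IGF signalling genes were higher in 5 of 21 and lower in 1 (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0346, adjusted p = 0.378 with estimated correlation). Igfbp4 stood at 1.21, Irs2 at 1.81 and Tbc1d4 at -0.72. Extracellular matrix genes had 5 of 30 higher and 1 lower, apoptosis regulators 4 of 31 and 1, and adipocyte progenitor markers 3 of 15 and 1. Adjusted over the list alone these were 6 and 1, 5 and 1, and 6 and 2 (camera adjusted p = 0.0113, 0.00415 and 0.0423, adjusted p = 0.383, 0.109 and 0.383 with estimated correlation). The list of repressed genes no longer passed without libraries 1 or 2 (control), 1 or 4 (Cre-labelled), with a mean of at least 50, without the 2 sparsest libraries or with the muscle covariate (camera adjusted p = 0.0556 to 0.0755), with a median of 0.28 that was 0.05 without control library 1, 0.42 and 0.13 without Cre-labelled libraries 2 and 4, 0.47 without the filter, 0.11 with a mean of at least 50 and 0.15 with the covariate. Insulin and IGF signalling did not pass without libraries 3 (control) or 3 (Cre-labelled) (camera adjusted p = 0.0661 to 0.101), extracellular matrix without control library 3 (adjusted p = 0.0527) and progenitor markers without libraries 2, 3 or 4 (control), 1, 2 or 3 (Cre-labelled), with a mean of at least 50 or with the muscle covariate (adjusted p = 0.0556 to 0.101). Cholesterol synthesis (1 of 23 higher and 1 lower), mural and smooth muscle (2 of 12 higher), Schwann and neural (1 of 10 higher and 2 lower) and circadian clock genes (1 of 19 lower) did not pass as lists, with the same counts adjusted over the list alone (camera adjusted p = 0.963, 0.242, 0.364 and 0.669). The same held for the unfolded protein response (2 of 18 higher, 2 adjusted over the list alone, camera adjusted p = 0.112), which passed without control library 2 (adjusted p = 0.0397). No cell cycle gene passed (0 of 22, 0 adjusted over the list alone, camera adjusted p = 0.103), and the list passed as higher without Cre-labelled library 3 (adjusted p = 0.00700). Nuclear receptors had 3 of 26 higher and 5 lower (4 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.734). They had a median of -0.01 and a mean of 0.19, which differ in sign. Erythrocyte markers, with 4 measured, were too few for a list test and none passed (0 adjusted over the list alone).

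**Figure D2:**
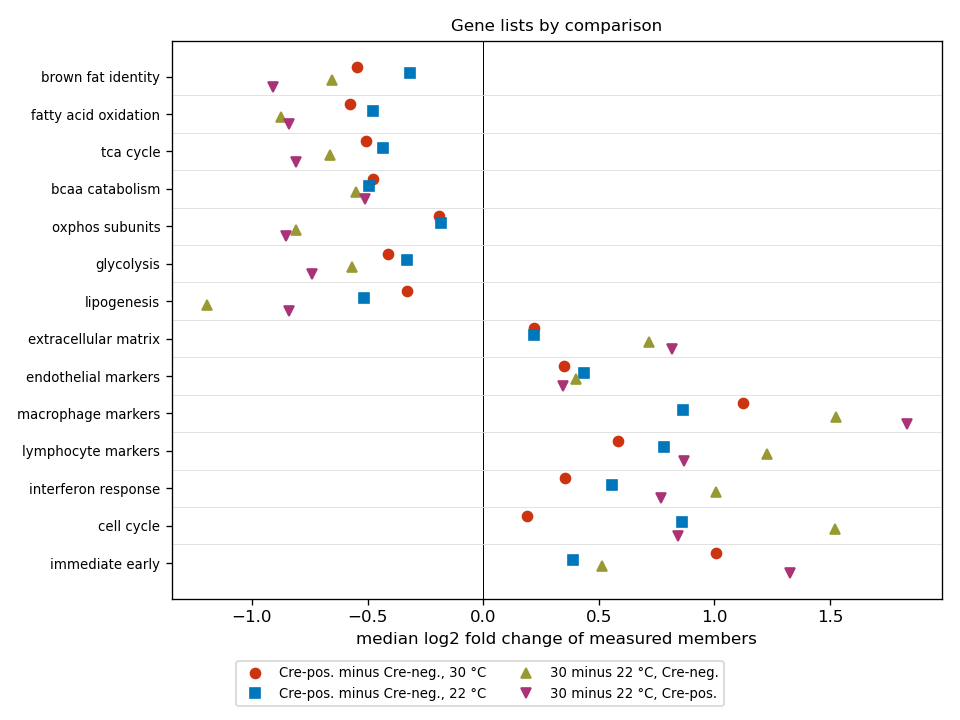
Median log2 fold change of the measured members of 14 gene lists (horizontal axis) in 4 comparisons, by Cre label at 30 °C and 22 °C and by temperature within each label (1 symbol each). Fatty acid oxidation genes lie left of 0 in all 4, at -0.58, -0.48, -0.87 and -0.84.

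At 22 °C, where brown fat is active, the same comparison by Cre label was led by Atp5g1, which went from 95.00 ± 44.6 to 2757 ± 909 normalised counts (SD, n = 4 each, log2 difference 4.88, SE 0.26, limma adjusted p = 1.62e-08). Acot3, a peroxisomal acyl-CoA thioesterase, rose from 11.4 ± 4.39 to 206 ± 15.6 (limma adjusted p = 2.19e-04) and Mest from 18.97 ± 9.57 to 254 ± 74.7 (adjusted p = 1.13e-05). Cdhr5, a cadherin-related protein, Adamts15, a secreted metalloprotease, and Srpx2, a secreted sushi repeat protein, rose too. Their log2 differences were 3.51, 3.30 and 3.10 (limma adjusted p = 3.13e-06, 2.20e-06 and 7.00e-07). Elovl3, a fatty acid elongase that brown fat makes in the cold, fell from 937 ± 599 to 53.9 ± 18.4 (14.9-fold, limma adjusted p = 2.34e-04), and Kng2 from 1724 ± 394 to 182 ± 54.01 (adjusted p = 7.67e-07). Acat3 and Acaa1b, which act on acyl-CoA, Acsm3, a medium-chain acyl-CoA synthetase, and Dhrs9, a retinol and steroid dehydrogenase, fell as well. Their log2 differences were -3.08, -2.67, -2.52 and -2.50 (limma adjusted p = 2.01e-04, 1.13e-05, 1.26e-06 and 0.00777). Over all genes 726 were higher and 618 lower by limma, 277 and 130 of them by at least 2-fold, and the groups did not overlap for 12.4% of genes. Without Cre-labelled 22 °C library 2 the counts were 1164 and 1192. They were 404 and 360 without Cre-labelled 22 °C library 3, 425 and 408 without Cre-labelled 22 °C library 1, and 430 and 384 without control 22 °C library 3. Fitted on the groups compared alone the counts were 276 and 249, and under quantile normalization 453 genes were higher.

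Most metabolic lists were lower at 22 °C too. Fatty acid oxidation had 13 of 27 genes lower and 1 higher (1 higher and 20 lower adjusted over the list alone, camera adjusted p = 1.92e-10, adjusted p = 0.229 with estimated correlation). Slc25a20 stood at -0.76 and Etfa, which passes electrons from these dehydrogenases to the respiratory chain, at -0.78 (limma adjusted p = 0.00327). The higher one was again Acot2 (0.61, limma adjusted p = 0.0382), a call lost without libraries 3 or 4 (control), 1, 2 or 4 (Cre-labelled), in the groups compared alone, without the trend, without the 2 sparsest libraries or with the muscle covariate (adjusted p = 0.0562 to 0.105). Branched-chain amino acid breakdown and the citric acid cycle had 14 of 23 and 9 of 24 lower, 18 and 19 adjusted over the list alone (camera adjusted p = 1.28e-11 and 3.78e-08, adjusted p = 0.209 and 0.308 with estimated correlation). Ppm1k stood at -1.07 (limma adjusted p = 2.87e-05). Suclg1 stood at -0.60 (limma adjusted p = 0.0104, and 0.0800 in the groups compared alone). Cs stood at -0.56 (limma adjusted p = 0.0131), a call lost without the filter, under quantile normalization or in the groups compared alone (adjusted p = 0.0569 to 0.711). Under quantile normalization Cs stood at -0.07, Suclg1 at -0.37 and Slc25a20 at -0.49. In brown fat identity 7 of 29 were lower and 2 higher (2 higher and 9 lower adjusted over the list alone, camera adjusted p = 2.18e-04, adjusted p = 0.209 with estimated correlation). Letmd1 stood at -0.86, the potassium channel Kcnk3 at -0.71 and Slc27a2 at -1.18 besides Elovl3. Respiratory chain subunits had 3 of 78 lower and Atp5g1 higher (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 4.03e-04, adjusted p = 0.609 with estimated correlation). Lipogenesis was lower as a list (1 of 23 higher and 4 lower, 1 higher and 6 lower adjusted over the list alone, camera adjusted p = 8.56e-04, adjusted p = 0.397 with estimated correlation). Glycolysis and cholesterol synthesis had 4 and 2 of 23 lower, 8 and 7 adjusted over the list alone (camera adjusted p = 0.00169 and 0.00266, adjusted p = 0.361 and 0.397 with estimated correlation). The respiratory chain no longer passed without control library 1 or under quantile normalization (camera adjusted p = 0.517 to 0.896), with medians of 0.01 and 0.02, and -0.38 and -0.11 without Cre-labelled libraries 2 and 3. Lipogenesis and glycolysis did not pass under quantile normalization (camera adjusted p = 0.143 and 0.175). Lipolysis passed as lower with 1 of 20 higher and 1 lower (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0360, adjusted p = 0.397 with estimated correlation), but not without libraries 1 (control), 2 or 3 (Cre-labelled), with a mean of at least 50, under quantile normalization or without the 2 sparsest libraries (adjusted p = 0.0545 to 0.607). Creatine and calcium cycling did not pass (1 of 12 lower, 1 adjusted over the list alone, median 0.03, camera adjusted p = 0.645). The split of these 8 libraries that exchanges library 2 of both groups gave 14 of 78 respiratory chain subunits lower, and medians there and by label were -0.42 and -0.18. They were -0.38 and -0.48 for fatty acid oxidation, -0.29 and -0.49 for branched-chain amino acids, -0.43 and -0.43 for the citric acid cycle, -0.19 and -0.32 for brown fat identity, -0.35 and -0.52 for lipogenesis, -0.25 and -0.33 for glycolysis and -0.21 and -0.25 for cholesterol synthesis. By label under quantile normalization the first 6 of these were -0.17, -0.31, -0.16, -0.17, -0.19 and -0.10. The median of lipogenesis was -0.83 without Cre-labelled library 1 and that of glycolysis -0.15 without library 3.

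Cell cycle genes were higher at 22 °C in the Cre-labelled libraries in 6 of 22, 12 adjusted over the list alone (camera adjusted p = 2.47e-07, adjusted p = 0.209 with estimated correlation). Among them were the mitotic genes Bub1b (1.33, limma adjusted p = 0.00203) and Top2a (1.84, adjusted p = 0.00382) and the proliferation marker Mki67 (1.48, adjusted p = 0.00520). Interferon response genes were higher in 9 of 24, 11 adjusted over the list alone (camera adjusted p = 1.00e-07, adjusted p = 0.229 with estimated correlation). Gbp3 stood at 1.11, Gbp2 at 0.91 and Ifit1 at 1.04. Macrophage markers were higher in 7 of 22 and lower in 1 (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.09e-06, adjusted p = 0.229 with estimated correlation). Csf1r, the receptor that macrophages need for survival, was higher (0.72, limma adjusted p = 0.00323), as was C1qb (0.87, adjusted p = 0.00876, and 0.0547 in the groups compared alone). Cd14 was lower (-1.18, limma adjusted p = 0.00112). Endothelial markers were higher in 6 of 16, 9 adjusted over the list alone (camera adjusted p = 3.71e-06, adjusted p = 0.229 with estimated correlation). Lymphocyte and adipocyte progenitor markers were higher in 4 of 13 and 3 of 15, 5 each adjusted over the list alone (camera adjusted p = 6.62e-04 and 0.00211, adjusted p = 0.229 each with estimated correlation). In the split that exchanges library 2 of both groups 9 endothelial markers were higher, and medians there and by label were 0.51 and 0.43. They were 0.52 and 0.56 for interferon genes, 0.41 and 0.46 for progenitors, 2.05 and 2.01 for skeletal muscle, 0.46 and 0.78 for lymphocytes, 0.20 and 0.86 for cell cycle and 0.14 and 0.86 for macrophages. Under quantile normalization lymphocytes and cell cycle had 0.48 and 0.55. Of the genes known to be repressed by BCL6, 4 of 23 were higher and 1 lower (5 higher and 2 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.139). Socs2 rose from 227 ± 121 to 1248 ± 324 (limma adjusted p = 5.32e-06). Cd44 rose by 1.34 and Id2 fell by 1.17. White fat genes did not pass as a list (camera adjusted p = 0.123) with 3 of 18 higher and 2 lower (4 higher and 2 lower adjusted over the list alone), but did with a mean of at least 50 or under quantile normalization (adjusted p = 0.00649 to 0.0273). The higher ones were Mest, Nnat (2.58, limma adjusted p = 3.06e-05) and the amino acid transporter Slc7a10 (2.49, adjusted p = 0.00601). Skeletal muscle genes had a median of 2.01, opposite in sign to 30 °C, with 1 of 42 past the threshold and 0 adjusted over the list alone (camera adjusted p = 1.42e-04, adjusted p = 0.574 with estimated correlation). The median was 1.05 and 3.12 without Cre-labelled libraries 1 and 2. Muscle scores spanned -2.95 to 0.0755 in the controls and -3.12 to 2.85 in the Cre-labelled libraries. The 1 gene was myoglobin Mb (1.62, limma adjusted p = 0.0428), whose call was lost without libraries 1, 3 or 4 (control 22 °C), 1 or 4 (Cre-labelled 22 °C), 1, 2, 3 or 4 (control 30 °C), without the filter, under quantile normalization, in the groups compared alone, without the trend or with robust estimation (adjusted p = 0.0503 to 0.139).

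The genotype differences at both temperatures share no library, but in 1 fit they share each gene's estimate of the spread. Genes higher in the Cre-labelled libraries at both temperatures numbered 268, where independent lists would share 41.0, and genes lower at both numbered 335 against 42.3. In separate fits for each temperature, added after the data were seen, they numbered 171 against 23.5 and 162 against 24.4. Acot3, Mest, Nnat, Atp5g1 and Socs2 were higher at both, Kng2, Acaa1b, Slc25a20, Letmd1 and Ppm1k lower at both. Only 6 genes were called in opposite directions. Across the 13176 genes the log2 differences at 30 °C and 22 °C correlated at r = 0.463. Genes are not independent replicates, so no p is given for the overlap or the correlation.

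Controls at 30 °C against 22 °C differed in muscle score too, so housing is not isolated. Elovl3 fell from 937 ± 599 to 7.65 ± 5.34 normalised counts (SD, n = 4 each, log2 difference -6.73, SE 0.55, limma adjusted p = 3.14e-07). Mfsd2a, a transporter of lysophospholipids, Acot1, Dio2, which makes active thyroid hormone, and Gldn, gliomedin, also fell. Their log2 differences were -5.82, -5.40, -4.73 and -4.41 (limma adjusted p = 3.50e-05, 4.27e-06, 1.65e-05 and 3.07e-06). Ucp1, named here after its values were seen, went from 88819 ± 26458 to 16596 ± 2078 (5.20-fold lower, limma adjusted p = 2.77e-06). Fras1 rose from 8.41 ± 5.80 to 204 ± 18.7 (limma adjusted p = 1.87e-06). Prnd held 0, 3.28, 0 and 0 at 22 °C and 122, 118, 129 and 59.9 at 30 °C (limma adjusted p = 4.00e-05). Fdx1l was listed at 0, 144, 0 and 0 at 30 °C against 374, 146, 245 and 257 at 22 °C (limma adjusted p = 0.00439). Adnp stood at 613, 12.4, 489 and 508 against 10.05, 4.98, 10.7 and 8.05 (limma adjusted p = 0.0333). The call for Adnp was lost without libraries 1, 2, 3 or 4 (control 22 °C), 1, 3 or 4 (control 30 °C), under quantile normalization, with robust estimation, without the 2 sparsest libraries or with the muscle covariate (limma adjusted p = 0.0531 to 0.0911). By limma 3012 genes were higher and 2987 lower at 30 °C, 1241 and 576 by at least 2-fold, and the groups did not overlap for 41.2% of genes.

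Nearly the whole respiratory chain fell at 30 °C in controls, 70 of 78 subunits, 72 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.58e-17, adjusted p = 0.308 with estimated correlation). Uqcrfs1 stood at -1.15, Sdhd at -1.03 and Ndufs8 at -0.97. Fatty acid oxidation fell in 24 of 27, 25 adjusted over the list alone (camera adjusted p = 1.79e-11, adjusted p = 0.197 with estimated correlation). Cpt2, a mitochondrial carnitine palmitoyltransferase, stood at -1.42 (limma adjusted p = 1.49e-07), Slc25a20 at -1.34 and Acaa1b at -2.91. Brown fat identity genes fell in 18 of 29 and rose in 2 (3 higher and 19 lower adjusted over the list alone, camera adjusted p = 5.86e-06, adjusted p = 0.197 with estimated correlation). Otop1 stood at -2.17, Letmd1 at -1.11 and glycerol kinase Gk at -3.20. Lipogenesis fell in 17 of 23 and rose in 2, the same counts adjusted over the list alone (camera adjusted p = 2.01e-05, adjusted p = 0.287 with estimated correlation). Agpat2 stood at -2.52, Elovl6 at -2.79 and the citrate carrier Slc25a1 at -2.15, while the desaturase Fads1 rose (1.21, limma adjusted p = 2.46e-05). The citric acid cycle and branched-chain amino acid breakdown had 21 of 24 and 18 of 23 lower, 22 and 18 adjusted over the list alone (camera adjusted p = 6.70e-08 and 1.92e-06, adjusted p = 0.287 and 0.197 with estimated correlation). Glycolysis had 13 of 23 lower and 3 higher, the same adjusted over the list alone (camera adjusted p = 0.00585, adjusted p = 0.368 with estimated correlation). Under quantile normalization Uqcrfs1, Sdhd, Ndufs8, Cpt2, Slc25a20 and Letmd1 stood at -0.62, -0.47, -0.55, -0.94, -0.84 and -0.64, and the last 3 lists did not pass (camera adjusted p = 0.419, 0.0604 and 0.516).

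Extracellular matrix genes rose at 30 °C in 24 of 30 and fell in 2 (26 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.63e-08, adjusted p = 0.197 with estimated correlation). The collagens Col3a1 stood at 1.29 and Col1a2 at 1.05. Macrophage markers rose in 19 of 22 (20 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.70e-08, adjusted p = 0.197 with estimated correlation). Csf1r stood at 1.14 and the integrin Itgam at 2.09. Cell cycle genes rose in 20 of 22 with 1 lower, the same adjusted over the list alone (camera adjusted p = 6.85e-08, adjusted p = 0.197 with estimated correlation). Mki67 stood at 2.57 and Top2a at 2.86. Interferon response genes rose in 18 of 24 and adipocyte progenitor markers in 8 of 15 with 1 lower (21, and 9 higher and 1 lower, adjusted over the list alone, camera adjusted p = 8.27e-08 and 9.17e-04, adjusted p = 0.200 and 0.197 with estimated correlation). White fat genes did not pass as a list (camera adjusted p = 0.164), with 7 of 18 higher and 5 lower, the same adjusted over the list alone, but did with a mean of at least 50 (adjusted p = 0.0471). Among them were the natriuretic peptide clearance receptor Npr3 (1.36), Nnat (3.21), Igfbp3 (1.27) and leptin, Lep (1876 ± 219.6 against 379 ± 176, limma adjusted p = 2.88e-05). Skeletal muscle genes moved with temperature, 22 of 42 higher, 25 adjusted over the list alone, with a median of 3.55 (camera adjusted p = 3.24e-05, adjusted p = 0.470 with estimated correlation). These included Mb (2.02), Ldb3 (2.76) and Actn2 (2.98). Ttn, Myh7 and Tnni2, all of the contractile apparatus, were among the genes highest at 30 °C, at 5.73, 5.04 and 4.80 (limma adjusted p = 0.0411, 0.0201 and 0.0372). The calls for Ttn and Tnni2 were lost without libraries 1 or 2 (control 22 °C), 1, 2, 3 or 4 (control 30 °C), under quantile normalization, without the trend, with robust estimation or without the 2 sparsest libraries, and Ttn also without the filter (limma adjusted p = 0.0508 to 0.131), and that for Myh7 without libraries 1 or 2 (control 22 °C), 1 (control 30 °C) or under quantile normalization (adjusted p = 0.0536 to 0.0590).

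In the Cre-labelled libraries, the genes highest at 30 °C over 22 °C included several known from macrophages. Clec4d, a C-type lectin, rose from 0.749 ± 0.871 to 116 ± 78.96 normalised counts (SD, n = 4 each, log2 difference 5.70, SE 0.68, limma adjusted p = 2.42e-05). Atp6v0d2, a subunit of a proton pump, Gpnmb, Mmp12, the macrophage elastase, and Trem2, a lipid-sensing receptor, rose by 5.60, 5.41, 5.30 and 3.82 (limma adjusted p = 3.89e-05, 3.57e-05, 2.18e-05 and 2.08e-04). In Cre-labelled 30 °C library 3 these genes stood apart from the other 3, with Clec4d at 14.01 against 96.4 to 192, Atp6v0d2 at 26.8 against 198 to 598, Gpnmb at 158 against 1065 to 4684, Mmp12 at 190.3 against 1648 to 3978 and Trem2 at 26.3 against 106 to 301. Egr3 rose by 4.03 (limma adjusted p = 4.88e-04). Ucp1 fell from 45894 ± 11771 to 5329 ± 1554 (8.68-fold, limma adjusted p = 5.45e-07). Mfsd2a, the asparaginase Aspg, Dio2, Acot1 and Gys2 had log2 differences of -4.60, -3.67, -3.63, -3.63 and -3.13 (limma adjusted p = 4.13e-04, 4.70e-07, 2.69e-04, 2.54e-04 and 1.25e-07). Macrophage markers were higher in 20 of 22, 20 adjusted over the list alone (camera adjusted p = 8.86e-14, adjusted p = 0.0710 with estimated correlation). Lgals3 stood at 3.68, Mpeg1 at 2.43, C1qb at 1.57 and Cd68 at 2.42. Immediate early genes were higher in 10 of 19, 10 adjusted over the list alone (camera adjusted p = 2.43e-04, adjusted p = 0.235 with estimated correlation). Fosl2 stood at 2.15 and Egr2 at 3.04. Extracellular matrix genes were higher in 23 of 30 (23 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.82e-12, adjusted p = 0.0530 with estimated correlation). Col3a1 stood at 1.07. Respiratory chain subunits fell in 77 of 78, 78 adjusted over the list alone (camera adjusted p = 3.88e-24, adjusted p = 0.193 with estimated correlation). Their median was -0.85, and -0.50 under quantile normalization. Ndufs8 stood at -1.12. Brown fat identity genes fell in 17 of 29 and rose in 1 (2 higher and 17 lower adjusted over the list alone, camera adjusted p = 5.89e-09, adjusted p = 0.0530 with estimated correlation). Otop1 stood at -2.71. Skeletal muscle genes had a median of 0.21 with 1 of 42 lower and 0 adjusted over the list alone, and did not pass (camera adjusted p = 0.791), but did without Cre-labelled 30 °C library 1 (adjusted p = 0.00842). By limma 1978 genes were higher and 2336 lower, and the groups did not overlap for 34.5% of genes.

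No group had Cre without flanked Bcl6, so effects of Cre and of BCL6 loss are not separated. The interaction is the difference by Cre label at 30 °C minus that at 22 °C. Metallothionein Mt2 was 2.09 higher in this sense (limma adjusted p = 0.00350), with 1005 ± 188 against 357 ± 122 normalised counts at 30 °C and 731 ± 118 against 1075 ± 221 at 22 °C (SD, n = 4 each). Acsl5, a long-chain acyl-CoA synthetase, was at 1.68 (limma adjusted p = 0.00249). In the opposite sense, Tusc3 stood at -3.39 (SE 0.29, limma adjusted p = 1.23e-05). Prss12, a secreted protease, stood at -3.50 (limma adjusted p = 5.64e-04) and Rgs11 at -3.12 (adjusted p = 9.21e-04). Cdsn, corneodesmosin, stood at -3.05 (limma adjusted p = 1.96e-05) and Ddah1, which degrades methylarginines, at -2.52 (adjusted p = 1.23e-05). Atp5g1, higher at both temperatures, was raised less at 30 °C (-2.23, limma adjusted p = 0.0114), and Myd88 had an interaction of 0.94 (adjusted p = 0.00959). The interactions of Mmd2 (3.02), Fosl2 (1.90), C3 (1.74), Zfr2 (-2.88), Fads1 (-1.17) and Cd14 (1.48) passed as well. Their limma adjusted p values were 0.0356, 0.0348, 0.0223, 0.0211, 0.0290 and 0.0256, and each call was lost in other settings. For Mmd2 this was without libraries 2, 3 or 4 (control 22 °C), 4 (Cre-labelled 22 °C), 1, 3 or 4 (control 30 °C), 1, 3 or 4 (Cre-labelled 30 °C), without the trend, with robust estimation or with the muscle covariate (limma adjusted p = 0.0520 to 0.0974), and for Fosl2 without libraries 2, 3 or 4 (control 22 °C), 1, 2 or 3 (Cre-labelled 22 °C), 1, 3 or 4 (control 30 °C), 1 (Cre-labelled 30 °C) or without the trend (adjusted p = 0.0520 to 0.0906). The call for C3 was lost without libraries 3 (control 22 °C), 3 (control 30 °C), 1 (Cre-labelled 30 °C) or under quantile normalization (limma adjusted p = 0.0555 to 0.0767), and for Zfr2 without control 30 °C library 3 or with the muscle covariate (adjusted p = 0.0547 to 0.0581). For Fads1 and Cd14 it was lost without libraries 3 (control 22 °C), 1 (Cre-labelled 22 °C), 1 or 3 (control 30 °C), 1 (Cre-labelled 30 °C) or with the muscle covariate, and Fads1 also without the trend (limma adjusted p = 0.0538 to 0.0751).

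Over all genes the interaction was positive for 23 and negative for 35, with 1387 at an unadjusted limma p under 0.05. The positive count was 40, 9 and 4 without control 22 °C libraries 1, 2 and 3. It was 15, 15 and 13 without Cre-labelled 22 °C libraries 1, 3 and 4. It was 6, 42, 6 and 10 without control 30 °C libraries 1 to 4, and 4 without Cre-labelled 30 °C library 1. The negative count was 62 and 17 without control 22 °C libraries 1 and 3, 20 and 23 without Cre-labelled 22 °C libraries 1 and 4, 17 and 17 without control 30 °C libraries 1 and 3, and 17 without Cre-labelled 30 °C library 1. As lists, immediate early genes and macrophage markers had a positive interaction, with 1 of 19 and 1 of 22 past the threshold, 4 and 1 adjusted over the list alone (camera adjusted p = 0.00304 and 0.0126, adjusted p = 0.981 each with estimated correlation). So did the unfolded protein response and cholesterol synthesis, with 0 of 18 and 0 of 23, 1 and 0 adjusted over the list alone (camera adjusted p = 0.0130 and 0.00749, adjusted p = 0.981 each with estimated correlation). Cell cycle and skeletal muscle genes had a negative one, with medians of -0.63 and -3.22 and 0 of 22 and 0 of 42 past the threshold, 0 each adjusted over the list alone (camera adjusted p = 3.82e-04 and 1.10e-09, adjusted p = 0.981 each with estimated correlation). The immediate early list did not pass without Cre-labelled 30 °C library 3 (camera adjusted p = 0.369), where its median was -0.02, nor macrophage markers without libraries 1 (control 22 °C), 3 (Cre-labelled 22 °C), 2 (control 30 °C), 4 (Cre-labelled 30 °C), without the 2 sparsest libraries or with the muscle covariate (adjusted p = 0.0506 to 0.271). The unfolded protein response did not pass without libraries 1 (control 22 °C), 4 (Cre-labelled 30 °C) or with the muscle covariate (camera adjusted p = 0.0554 to 0.0689), nor cholesterol synthesis without libraries 3 (Cre-labelled 22 °C) or 4 (Cre-labelled 30 °C) (adjusted p = 0.0510 to 0.0574) and cell cycle under quantile normalization (adjusted p = 0.0547). Without Cre-labelled 30 °C library 1 the muscle median was -1.85. Brown fat identity (camera adjusted p = 0.390) and fatty acid oxidation (adjusted p = 0.890, median -0.07 and mean 0.04) did not pass as different between temperatures. Under quantile normalization both did, with medians of -0.31 and -0.26 (camera adjusted p = 0.0101 and 9.84e-04). Among other lists, negative passes were those of the respiratory chain without control 22 °C library 1, under quantile normalization or with the muscle covariate (camera adjusted p = 1.13e-05 to 0.0103), citric acid cycle and glycolysis without Cre-labelled 22 °C library 3 or under quantile normalization (adjusted p = 8.48e-05 to 0.0136), branched-chain amino acid breakdown under quantile normalization (adjusted p = 0.0354), creatine and calcium cycling without Cre-labelled 30 °C libraries 2 or 3 or with a mean of at least 50 (adjusted p = 0.0402 to 0.0435) and the interferon response without libraries 2 or 4 (Cre-labelled 22 °C), 2 or 4 (control 30 °C), 1 or 3 (Cre-labelled 30 °C), with a mean of at least 50 or without the 2 sparsest libraries (adjusted p = 0.00915 to 0.0487).

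Whether genes moved by Cre label at 30 °C are those moved by housing temperature was asked from the comparison by label at 30 °C and the comparison by temperature in controls, which share the 4 control libraries at 30 °C. Of 985 genes called in both, 325 were higher by label and higher at 30 °C (170.3 by chance from independent lists) and 322 were lower in both (204 by chance). The opposite combinations held 118 (169 by chance) and 220 genes (206 by chance). Of the lists past the threshold in both comparisons, all but skeletal muscle (medians -1.36 and 3.55) moved the same way. Across the 13176 genes the log2 differences had a correlation of -0.0099 and a covariance of -0.00405. In 100 simulations of unchanged groups sharing the same controls, these averaged -0.500 and -0.0419, so the covariance lay 0.0378 above the simulated one. With the shared controls divided between the comparisons in 6 ways, the correlation ran from -0.0213 to 0.106 and the covariance averaged 0.0204.

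The BCL6 binding sites in control brown fat were compared with the genes that changed. The authors' list holds 3022 peaks of 180 bp (mm10), of which 1262 (41.8%) lie in introns, 1057 (34.98%) between genes, 485 (16.05%) at promoters and 92 (3.04%) in exons. The authors' peak scores ran from 4.11 to 170 with a median of 5.18. Among the 5 highest were the peaks nearest Ntpcr (chr8 125747530-125747710, score 170), Socs2 (chr10 95416839-95417019, score 123, 72 bp upstream of the start) and Mir3970 (chr19 33274534-33274714, 83.3). Within 10 kb of a start lay 1264 peaks, nearest to 1210 genes. Of the genes higher in Cre-labelled libraries at 30 °C, 90 of 745 had such a peak, 12.1%, against 857 of 11529, 7.43%, of genes not past the threshold. The odds ratio was 1.71 (95% interval 1.34 to 2.16, Fisher's exact p = 1.42e-05, 8.49e-05 after Benjamini-Hochberg adjustment over 6 tests). Of the lower genes 74 of 902 had one, 8.20% (odds ratio 1.11 (0.857 to 1.43), Fisher's exact p = 0.393, adjusted 0.472). At 22 °C the higher genes had a peak in 79 of 726, 10.9% (odds ratio 1.49 (1.15 to 1.90), Fisher's exact p = 0.00208, adjusted 0.00624). The lower genes had one in 44 of 618, 7.12% (odds ratio 0.933 (0.666 to 1.28), Fisher's exact p = 0.755, adjusted 0.755), and the remaining genes in 898 of 11832, 7.59%. Higher set against lower genes directly, a test added after the data were seen, gave odds ratios of 1.54 (1.10 to 2.16) at 30 °C (Fisher's exact p = 0.0103, adjusted 0.0205) and 1.59 (1.07 to 2.40) at 22 °C (Fisher's exact p = 0.0177, adjusted 0.0266).

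Named genes with a peak within 10 kb of their start included Socs2, Atp5g1 with 2 peaks (chr11 96076816-96076996, score 48.6, and chr11 96070429-96070609, score 47.9) and Acot1 (chr12 84009072-84009252, promoter, 15.6). Others were Lep (chr6 29059868-29060048, promoter, 19.8), Acot3 (chr12 84052689-84052869, 5' untranslated region, 4.47), Gbp3 (chr3 142559953-142560133, promoter, 7.33), Nnat (chr2 157561155-157561335, exon 2, 5.90) and Top2a (chr11 99024225-99024405, promoter, 4.11). Of these, all but Lep were higher in Cre-labelled libraries at 30 °C or 22 °C. Acaa1b (chr9 119155788-119155968, intron 2, 4.65), Dhrs9, Id2, Tbc1d4 and Slc36a2 (scores 4.47, 4.29, 8.22 and 4.65) carried peaks and were lower, as was Acsl5 (chr19 55253828-55254008, 5' untranslated region, 5.18) at 22 °C (-2.02). In 3 classes of mean expression, from lowest to highest, the odds ratios of the higher genes at 30 °C were 1.61, 1.81 and 1.63 (Fisher's exact p = 0.0655, 0.00269 and 0.0144), and the lower genes had 1.99 in the lowest (p = 0.0114). Within 1 kb of a start the higher genes did not pass as different from the rest at 30 °C (odds ratio 1.09, Fisher's exact p = 0.553) or at 22 °C (1.24, Fisher's exact p = 0.169). With only the higher-scoring part of the list the odds ratios were 3.05 and 2.83 (Fisher's exact p = 4.55e-12 and 2.74e-10), and with genes at an adjusted p under 0.01 2.08 and 2.54. These tests treat genes as independent, and the list comes from 1 library with no replicate check.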

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

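The tests of other splits of the samples and of a mislabelled library were chosen before their results were seen, those on macrophages, adipocytes and the interaction without the common difference after. Libraries far from the other 3 of their group were found by Dixon's ratio, the gap to the nearest value over the range, against its 95% critical value. It was passed in 25 of 588 groups (4.25%), and chance alone passes about 1 in 20. Values are normalised counts of that library against those of the other 3, then the ratio, which was taken on log2 values. Lowest of their group were Acot2 in control 22 °C library 4 (667 against 883 to 927, 0.854), Adnp in control 30 °C library 2 (12.4 against 489 to 613, 0.941), C3 in control 22 °C library 1 (7796 against 11743 to 12595, 0.854) and Egr3 in Cre-labelled 22 °C library 2 (3.46 against 43.3 to 57.97, 0.889). Also lowest were Fdx1l in Cre-labelled 30 °C library 1 (0 against 146 to 174, 0.966), Gbp3 in Cre-labelled 30 °C library 4 (767 against 1058 to 1118, 0.854), Kcnk3 in Cre-labelled 22 °C library 3 (3469 against 4369 to 4521, 0.870) and Lgals3 in control 30 °C library 2 (187 against 278 to 295, 0.871). At the bottom of their groups too were Mpeg1 in control 22 °C library 3 (87.2 against 123 to 129, 0.875), Prnd in control 30 °C library 4 (59.9 against 118 to 129, 0.892), Slc7a10 in Cre-labelled 22 °C library 2 (363 against 1706 to 1908, 0.933) and Zim1 in control 22 °C library 2 (12.6 against 21.8 to 23.3, 0.886). Highest of their group were Acot4 in control 30 °C library 2 (109 against 16.2 to 20.5, 0.881), Atf3 in control 30 °C library 2 (226 against 42.4 to 48.98, 0.914), Fdx1l in control 30 °C library 2 (144 against 0, 1.00) and Irs2 in Cre-labelled 30 °C library 3 (829.8 against 331 to 380.2, 0.849). Also highest were Itgam in control 22 °C library 1 (26.6 against 15.8 to 16.8, 0.885) and Prnd in control 22 °C library 2 (3.28 against 0, 1.00). Among list scores, highest were oxphos subunits in control 22 °C library 1 (1.05 against 0.238 to 0.349, 0.862), skeletal muscle in control 30 °C library 1 (2.05 against 1.25 to 1.31, 0.923), lipolysis lipid droplet in control 22 °C library 1 (0.457 against 0.232 to 0.250, 0.921) and erythrocyte markers in control 22 °C library 1 (0.684 against -0.425 to -0.251, 0.843). Lowest were white fat enriched in control 30 °C library 4 (-0.208 against 0.0889 to 0.133, 0.870), schwann neural markers in Cre-labelled 22 °C library 2 (-0.786 against -0.211 to -0.125, 0.871) and circadian clock in control 30 °C library 4 (-0.285 against 0.00509 to 0.0573, 0.848).

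The difference by Cre label differed between temperatures, by the interaction in limma, for 18 named genes. Values are log2 differences at 30 °C and 22 °C, the interaction and its limma adjusted p. They held for Acsl5 (-0.34 and -2.02, 1.68, 0.00249), Atp5g1 (2.65 and 4.88, -2.23, 0.0114), C3 (0.03 and -1.71, 1.74, 0.0223) and Cd14 (0.31 and -1.18, 1.48, 0.0256). Others were Cdhr5 (1.03 and 3.51, -2.48, 0.0256), Cdsn (-1.55 and 1.50, -3.05, 1.96e-05), Ddah1 (-1.78 and 0.73, -2.52, 1.23e-05) and Fads1 (0.57 and 1.74, -1.17, 0.0290). It was also found for Fosl2 (1.75 and -0.15, 1.90, 0.0348), Gys2 (-4.09 and -2.28, -1.81, 0.00975), Mmd2 (2.51 and -0.51, 3.02, 0.0356) and Mt2 (1.54 and -0.55, 2.09, 0.00350). Further genes were Myd88 (0.62 and -0.32, 0.94, 0.00959), Prss12 (-2.72 and 0.78, -3.50, 5.64e-04), Rgs11 (-3.79 and -0.68, -3.12, 9.21e-04) and Srpx2 (0.69 and 3.10, -2.41, 0.00250). Last were Tusc3 (-3.86 and -0.47, -3.39, 1.23e-05) and Zfr2 (-1.66 and 1.22, -2.88, 0.0211).

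Bcl6 RNA was higher in the Cre-labelled libraries. A single mislabelled library is argued against by groups without overlap at both temperatures, which fixed the sign in fits without 1 library. Higher Bcl6 passed in 16 of 16 (lowest log2 difference 1.06, highest limma adjusted p 0.0174). More macrophages, whose score was higher by 0.720 at 22 °C and 1.14 at 30 °C (exact permutation p = 0.0286 each), might account for it and stay open. Taking the macrophage score off log2 Bcl6, as if Bcl6 rose by as much as the score, left a difference of 0.980 at 22 °C (exact permutation p = 0.0857) and 0.186 at 30 °C (exact permutation p = 0.686). RNA from a Bcl6 gene lacking its deleted part was not tested, as values do not divide the gene, nor was an exchange of all labels.

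Fatty acid oxidation genes were lower in the Cre-labelled libraries. A lower share of all adipocytes is argued against as the whole cause. The score minus a general adipocyte score, chosen after seeing the data, differed by -0.504 at 30 °C and -0.495 at 22 °C (exact permutation p = 0.0286 each, the minimum). The general score differed by 0.0127 and -0.0348. It does not test a shift of brown to white adipocytes, left open. A change by Cre label within adipocytes is a hypothesis, found and tested on the same data.

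Counts of changed genes were set against other splits of the same samples into groups of the same sizes. In each comparison of 2 groups 1 of 35 splits, the labelled one, gave as many genes, the smallest share the design allows. That argues against chance for genotype at 30 °C and for temperature within each label. It called 1647 genes for genotype at 30 °C (highest other 2), 1344 at 22 °C (1221), 5999 for temperature in controls (2) and 4314 in Cre-labelled libraries (104). At 22 °C the splits with 1221 and 579 genes exchange Cre-labelled library 2 with control libraries 2 and 4, which points to a structure of these samples beside the label. The first shared 202 genes with the labelled split. For the interaction, drawn splits keep the difference by label and count it as an interaction where labels are exchanged at 1 temperature, so the 4 of 100 with as many as its 58 genes (highest other 1287) decide nothing. With the difference common to both temperatures taken out first, 1 of 100, the labelled one, gave as many (highest other 2), which argues against chance for that count.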

How the results depend on the processing

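The muscle covariate, omission of 2 libraries, lists without each library and overlap from separate fits were chosen after seeing the data, other alternatives before. Across alternatives other than single libraries left out, no named gene changed direction, and of 177 named differences 0 to 12 lost their call per setting: 0 with a pseudocount of 8 and with a mean of at least 50 (172 compared), 4 without a filter, 9 under quantile normalization, 8 without the trend, 6 with robust estimation, 5 without the 2 sparsest 22 °C libraries, 12 with the muscle covariate, 5 of them muscle genes, and 8 (1 gained) of 161 in the groups compared alone. With each library left out, 93 of 2832 were lost and 1 gained, and of 2240 list results 37 were lost, 22 gained and 1 changed the direction of the test, while medians changed sign in 4. Of 140 list results, 79 lost their call with an estimated correlation, which left 0 called in any comparison. Apart from that, lists lost and gained were 0 and 0 with a pseudocount of 8 and 0 and 2 without a filter. They were 6 and 5 of 135 with a mean of at least 50 and 5 and 2 without the 2 libraries. Quantile normalization gave 11 and 10 (3 more changed direction) and the covariate 9 and 4 (2 more). The cause of the other changes was not tested. Raw depth is unknown, so low genes limit what can be seen.

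Without the 2 sparsest 22 °C libraries, the counts of genes were 1329 higher and 1466 lower for genotype at 30 °C, 1147 and 1197 at 22 °C, and 82 and 98 for the interaction. In the groups compared alone, 1123 were higher at 30 °C, and 276 higher and 249 lower at 22 °C. Quantile normalization gave 453 higher at 22 °C and 54 negative interactions, and a pseudocount of 8 gave 55. Without the trend the interaction had 14 and 23, and with the muscle covariate 12 and 22. The difference of Bcl6 between temperatures in controls was 0.80 in the groups compared alone (limma adjusted p = 0.0547), 0.76 without the 2 libraries (adjusted p = 0.0539) and 0.57 with the covariate (adjusted p = 0.165). Lists called lower were 6 for genotype at 30 °C with the covariate, and under quantile normalization 5 at 22 °C and 5 for temperature in controls. For the interaction they were 4 with a mean of at least 50 and 7 under quantile normalization. At a threshold of 0.01 the genotype differences shared 95 higher and 135 lower genes, and in separate fits 171 and 162. The correlation of genotype at 30 °C with temperature was 0.0207 with a pseudocount of 8, a change of sign, and -0.0879 under quantile normalization. Within 1 kb, the odds ratio of peaks near higher genes was 1.09 at 30 °C and 1.24 at 22 °C (Fisher's exact p = 0.553 and 0.169).

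With 1 library left out, medians changed sign for skeletal muscle at 30 °C (-1.36, and -2.26 to 0.248 over the libraries left out) without Cre-labelled 30 °C library 1 (0.248, camera adjusted p = 0.896), creatine and calcium cycling at 30 °C without the same library (0.0289, adjusted p = 0.135), the respiratory chain at 22 °C without control 22 °C library 1 (0.0133, adjusted p = 0.896) and immediate early genes in the interaction without Cre-labelled 30 °C library 3 (-0.0240, adjusted p = 0.369). With the muscle covariate they did for skeletal muscle at 30 °C (0.148, camera adjusted p = 0.357) and in the interaction (0.160, adjusted p = 0.714), and for creatine and calcium cycling at 30 °C (0.00161, adjusted p = 0.192). The score is made of the muscle genes, 3 of them shared with the creatine list, so their outcome was fixed by construction. Under quantile normalization the median or direction changed for the respiratory chain at 22 °C (0.0211, camera adjusted p = 0.517), lipolysis at 22 °C (-0.00742, adjusted p = 0.607) and branched-chain amino acid breakdown in the interaction (-0.110, adjusted p = 0.0354).

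With each library left out, genes higher ran from 452 to 982 and lower from 559 to 1135 for genotype at 30 °C, and from 404 to 1164 and 360.0 to 1192 at 22 °C. The interaction ran from 4 to 42 and from 17 to 62, temperature in controls from 2476 to 3310.0 and 2606 to 3200.0, and temperature in Cre-labelled libraries from 1500.0 to 2315 and 1832 to 2626. The log2 difference of Bcl6 ran from 1.06 to 1.47 at 30 °C and 1.57 to 1.99 at 22 °C, and between temperatures in controls from 0.67 to 1.09. Lists called lower for genotype at 30 °C ran from 6 to 10, and those of the interaction from 1 to 4 positive and 2 to 4 negative.

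Replicate numbers do not pair the libraries: of 24 pairs of libraries with the same number, 6 had deviations correlated above 0.1 (range -0.480 to 0.238), and the best match was the library of the same number in 12 of 48 cases. With the replicate block the interaction had 5 positive and 19 negative genes, 7 of the 177 named differences lost their call and 1 gained one, and no list call changed.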

Other observations

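The genes and the tests of this part were chosen after their values were seen. Peg3, Usp29 and Zim1, imprinted neighbours on chr7, were higher in the Cre-labelled libraries at both temperatures. Peg3 rose by 2.61 at 30 °C (limma adjusted p = 1.57e-06) and 2.46 at 22 °C (adjusted p = 2.85e-06). Usp29 rose by 2.76 (limma adjusted p = 0.00229) and 3.32 (adjusted p = 6.39e-04), and Zim1 by 2.30 (adjusted p = 1.62e-05) and 2.87 (adjusted p = 1.59e-06). Acyl-CoA thioesterases of the chr12 cluster moved as well. Acot3 rose by 4.36 (limma adjusted p = 1.06e-04) at 30 °C. Acot4 rose by 2.65 at 30 °C (limma adjusted p = 5.20e-04) and stood at 1.16 at 22 °C (adjusted p = 0.0850), where leaving out control 30 °C library 2 gave adjusted p = 0.00170 and the groups compared alone gave 0.0139. Gys2 was lower at 22 °C too (-2.28, limma adjusted p = 2.74e-06). Paralogs in this cluster share sequence, so values are uncertain.

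Both neighbours of Ucp1 (chr8 83290348-83298456) were higher in the Cre-labelled libraries, although Ucp1 was lower at 30 °C and at 22 °C (-0.94, limma adjusted p = 0.0227). The call for Ucp1 at 22 °C was lost without libraries 2 (control) or 1 or 3 (Cre-labelled), under quantile normalization or in the groups compared alone (limma adjusted p = 0.0628 to 0.0981). Tbc1d9 (chr8 83165352-83272940) rose 1.87-fold at 30 °C (limma adjusted p = 0.0171) and 1.88-fold at 22 °C (adjusted p = 0.0204). Its call was lost at 30 °C without libraries 1 (control) or 4 (Cre-labelled) (limma adjusted p = 0.0530 to 0.0649), and at 22 °C without Cre-labelled library 4, under quantile normalization or in the groups compared alone (adjusted p = 0.0579 to 0.0795). Elmod2 (chr8 83312632-83332490) rose 2.09-fold (limma adjusted p = 0.00240) and 1.91-fold (adjusted p = 0.00766). The next genes were not higher: Rnf150 stood at -1.19 and -0.59, and Scoc at -0.36 and -0.33.

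A candidate explanation is extra copies of the Ucp1 region brought by a Cre transgene. Such a pair of higher neighbours at both temperatures was found around 12 of 13120 genes (0.0915%), but its rarity does not tell extra copies from another cause, and the construct is not given in the sources used here, so this stays open. So does BCL6 bound at these genes: 0 peaks lay within 50 kb of them, but 1 library may miss sites.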
